A study of Drosophila melanogaster with 20 samples.

How the data were processed

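Drosophila melanogaster wings and salivary glands, labelled female, were sequenced in 20 libraries, 2 for each of 10 groups of tissue, genotype and time. EcR-RNAi tissue carried a constitutive driver, reached through a vestigial-GAL4 and recombinase cassette, with hairpin and GFP transgenes. WT tissue carried none of these, so differences between genotypes include those between the lines. Per the labels, libraries were made from total RNA with a Tecan kit, and the submitters' processing notes name STAR 2.7.3a, SAMtools 1.9, DESeq2 without a version, and the dm6 genome.

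The authors deposited a matrix named as counts whose values are RPKM, reads relative to gene length and library size. Within each library the values are whole multiples of a step, and the step gave the reads: all 65034 low values tested (up to 20 reads) lay within 0.1 of a whole read. The lengths implied matched the gene span with introns within 1% for 99.9% of 10810 genes, against 17.8% for the exonic length. The authors' deposited result tables give log2 fold changes with standard errors, p-values with adjusted p-values, and a baseMean, a mean of scaled counts in another unit. Their fold changes are of the group named first over the second and were turned to the direction used here. The matrix held 17606 genes, of which 4 without values were left out, and no column was left unassigned. Positions are those of dm6.

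The tests planned before the data were examined (edgeR's quasi-likelihood test, with a DESeq2 Wald test and edgeR glmTreat as alternatives) were not used, because the matrix is not one of counts. The planned tests were replaced after the unit was known by limma 3.58.1 in R 4.3.3. Reads relative to library size (RPM) were scaled by TMM factors (trimming 30% of log ratios and 5% of levels), 1 was added, and log2 values were fitted with one mean per group over all 20 libraries, with moderated variances (trend and robust). This left 10 residual degrees of freedom and a median of 3.42 prior degrees of freedom. Genes were tested if they reached 0.559 scaled RPM, 10 reads at the median depth, in at least 2 libraries and 15 reads in total, which kept 10172 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change of at least 1 in size. The median standard error was 0.287 for comparisons of groups and 0.406 for interactions. Figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

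The comparisons were the WT intervals within each tissue, wing against gland at each WT time, EcRi against WT at each time and tissue, the EcRi intervals, and 6 interactions. Interactions give the EcRi change minus the WT change over time, the wing effect of EcR-RNAi minus the gland effect, or the wing change minus the gland change. Gene lists for 32 functions and cell types were fixed before the data were examined. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, then with estimated correlation and with fry. Of 608 list tests 222 passed with the preset correlation and 47 of those also with an estimated one; fry, which asks only whether a list moves on balance one way, called 268, of which 172 were shared with the preset test. Counts adjusted over the list alone are given where they differ from the counts over all genes tested.

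Genes were named by a rule fixed before the data were examined: EcR and any cascade member, w, up to 4 changed members of each other list with at least 5 scaled RPM in the higher group, and the 6 genes that rise most and the 6 that fall most with at least 20 and no overlap between libraries. After the data were seen, allowed genes whose calls survived leaving out each library were preferred. Genes outside the rule are marked. In simulated reads at the same depth, 86 to 90 of 100 genes changed 4-fold were called. So were 13 to 37 of 100 changed 2-fold, none in the wrong direction, and 4 to 14 unchanged genes. Equal spread was simulated in all groups, unlike the data, and changes only from 5 scaled RPM, so these rates may not hold.

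Alternatives were other scalings (median of ratios, and TMM without glue and 71E genes), filters, fold minimum, libraries in the fit, a replicate block and leaving out each library. Chosen after the data were seen were voom, log2(RPKM + 0.1), pseudocounts of 0.25 and 4, limma treat, array weights, leaving out WT gland -30 h replicate 2 throughout, and leaving out genes within reach of gland carry-over or fat body markers. Shares of reads carry 95% Wilson intervals, and a gene at 0 in a library is below the limit of 3 reads, 0.133 to 0.201 RPM. The labels pair no libraries and give no batch, so no batch was compared.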

Results

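RNA of Drosophila melanogaster wings and salivary glands was measured by total RNA sequencing in 20 libraries from animals labelled female. The sex of some pools is left open by roX1 reads (given below). The larval wing is an epithelium that goes on to form the adult wing, and the salivary gland is a secretory tissue that makes the glue proteins and is later destroyed. Tissue was taken at -30, -6 and +6 hours relative to puparium formation, as timed larvae, wandering larvae and staged prepupae. Wild-type (WT) tissue covered all 3 times. Tissue expressing a double-stranded RNA hairpin against EcR, the ecdysone receptor subunit, covered -30 and -6 h and is called EcRi below. Each of the 10 groups held 2 libraries, each pooled from at least 60 wings or glands according to the labels. The labels do not say whether the 2 libraries of a group came from separate sets of animals, so each p-value measures only the spread between libraries. That spread was pooled for each gene over all 10 groups and not taken from the compared groups alone. The libraries held 14936845 to 22611739 reads recovered from the deposited values, and between 6354 and 11472 genes with at least 1 read. The lowest of these gene numbers was that of replicate 2 of the WT gland at -30 h, whose other replicate showed 10996 genes at a similar depth. Its replicates differed by a median of 0.65 in log2 over genes, against 0.129 to 0.286 in the other groups.

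Levels are given as scaled RPM, that is reads relative to library size after TMM scaling (mean ± SD, n = 2), and changes as log2 fold changes ± standard error of the limma fit. Glue-rich libraries have small TMM factors, so scaled RPM there lie far above unscaled RPM. Genes are said to have risen or fallen only where they passed limma's test with at least a 2-fold change. In each of the 337 named changes of this kind the libraries of the 2 groups did not overlap; chance gives this for 33.3% of unchanged genes, but these genes were chosen for their calls.

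EcR itself (FBgn0000546, chromosome 2R, 6087873 to 6169087 of dm6) changed with time in opposite directions in the WT tissues. In the WT gland it stood at 289.9 ± 16.3 at -30 h, 1294 ± 36.7 at -6 h and 178 ± 14.4 at +6 h. In the WT wing it stood at 331 ± 23.6, 178 ± 23.9 and 568 ± 51.7 at the same times. EcRi glands held 291 ± 14.9 at -30 h and 219 ± 39.4 at -6 h, and EcRi wings held 200.2 ± 20.2 and 126 ± 1.32. EcRi therefore differed from WT by -2.57 ± 0.14 in the gland at -6 h, a fall. The gland libraries labelled EcRi at -30 h showed no lower EcR level (0.01 ± 0.14, adjusted p = 0.997). The wing differences, -0.73 ± 0.14 at -30 h (adjusted p = 0.0125) and -0.49 ± 0.14 at -6 h (adjusted p = 0.134), did not reach 2-fold. Reads from the hairpin would be counted with EcR where its sequence lies in the gene, so these values do not measure the loss of the endogenous mRNA alone. The white gene (w), whose copies mark many fly transgenes, separated the genotypes in every comparison, with 319 ± 14.9 and 444 ± 47.7 in EcRi wings, 531 ± 89.5 and 638 ± 35.6 in EcRi glands, and at most 17.4 in any WT group.

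**Figure D1:**
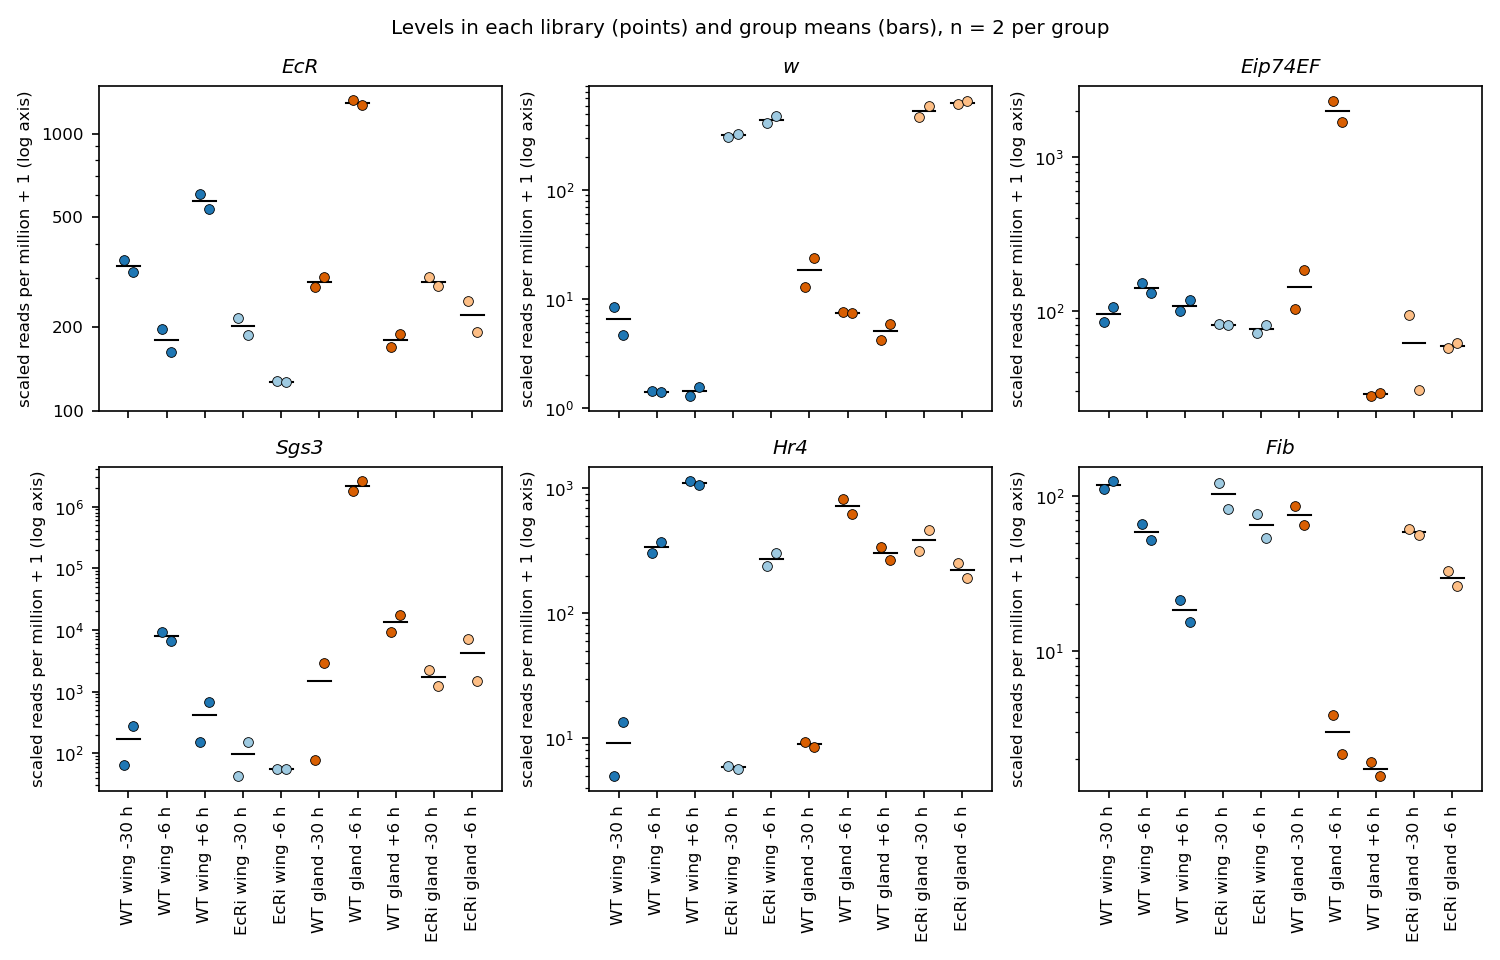
Levels of EcR, w, the ecdysone-induced factors Eip74EF and Hr4, the glue gene Sgs3 and the nucleolar gene Fib in all 20 libraries, as scaled RPM plus 1 on a log axis, with points for libraries and bars for group means. EcR peaks in the WT gland at -6 h at 1294 scaled RPM, and the group mean of w exceeds 17.4 only in EcRi groups.

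The gland comparison from -30 h to -6 h follows the secretory tissue into the wandering stage. Ecdysone-response regulators and 8 of 13 glue genes rose, while genes for DNA replication and for making ribosomes fell. Eip78C, a nuclear receptor of the ecdysone cascade, rose by 8.84 ± 0.44 and the nuclear receptor gene Hr4 by 6.32 ± 0.35. The glue gene Sgs3 rose by 12.14 ± 1.32, from 1484 ± 1989.6 to 2179193 ± 543710.5 scaled RPM. In all, 3535 of 10172 genes changed, 1840 higher and 1695 lower. A fit of only the compared libraries gave 1055 genes, and array weights 1806.

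Within the cascade list of transcription factors and early genes, 11 of 17 members rose, with 12 adjusted over the list alone (adjusted p = 1.1e-05, and adjusted p = 0.0202 with estimated correlation). EcR rose by 2.16 ± 0.14, the ETS factor Eip74EF by 3.87 ± 0.39, the nuclear receptors Eip75B and Hr39 by 3.78 ± 0.19 and 3.81 ± 0.57, and the ABC transporter gene E23 by 6.49 ± 0.55. Eip63F-1, which encodes a calcium-binding protein, rose by 4.28 ± 0.21. Glue genes went both ways: 8 of 13 members rose and 4 fell (adjusted p = 0.261). Sgs1, Sgs5 and the Sgs5 neighbour CG7587 rose by 11.44 ± 1.05, 11.63 ± 1.04 and 12 ± 1.54. The 4 that fell, named after their values were seen, were the early glue-cluster genes ng1 (-5.26 ± 0.46), ng2 (-4.81 ± 0.43), ng3 (-3.81 ± 0.50) and Pig1 (-1.78 ± 0.40). Late puff genes of region 71E, induced later in prepupal glands, also rose early, with 7 of 10 passing (adjusted p = 0.0578), among them Eig71Ea at 7.45 ± 1.22. Cell death genes followed: 7 of 10 members rose (adjusted p = 0.0048, and adjusted p = 0.558 with estimated correlation), including Buffy of the Bcl-2 family (6.05 ± 0.30), the apoptosome gene Dark (4.58 ± 0.68) and the death activator rpr (4.43 ± 0.38). In the autophagy list, 11 of 19 members rose and 1 fell (adjusted p = 0.00968, and adjusted p = 0.404 with estimated correlation), with the initiation gene Atg13 at 5.31 ± 0.96 and the protease gene Atg4b at -2.99 ± 0.21. Without WT gland -30 h replicate 2, Hr39 rose by 2.38, Dark by 2.886 and Atg13 by 2.886.

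For DNA replication, 21 of 28 members fell (adjusted p = 1.92e-09, and adjusted p = 0.00565 with estimated correlation), with the helicase subunits Mcm2 and Mcm5 at -3.42 ± 0.30 and -3.23 ± 0.20. For mitochondrial ribosomal proteins, 48 of 71 members fell (adjusted p = 7.54e-13, and adjusted p = 0.00131 with estimated correlation), mRpL3 among them at -3.59 ± 0.30. For ribosome biogenesis, 20 of 24 members fell (adjusted p = 7.54e-13, and adjusted p = 0.0202 with estimated correlation), with Fib and Nop60B, which modify ribosomal RNA, at -4.71 ± 0.30 and -4.61 ± 0.16. The matrix metalloprotease gene Mmp2 rose by 6.24 ± 0.45, while the collagen IV gene vkg fell (-3.56 ± 0.35), as did the glutathione transferases GstD1 (-5.02 ± 0.33) and GstD2 (-6.30 ± 0.39). Thor, the inhibitor of translation initiation, rose by 3.72 ± 0.25, the peptidoglycan recognition gene PGRP-SB2 by 10.26 ± 0.93 and Fbp1, a fat body gene, by 8.07 ± 0.76. In the list of Hippo and insulin pathway growth genes, 6 of 17 members rose (adjusted p = 0.0218, and adjusted p = 0.561 with estimated correlation). The largest falls among abundant genes included CG14850 (-8.63 ± 0.97) and nol (-5.88 ± 0.61). Glue genes other than ng1 to ng4 and Pig1 took 70.6% and 75.8% of the reads of the WT gland at -6 h. A single read there therefore counts for more scaled RPM than elsewhere. A median-of-ratios scaling moved the median of all genes from 0.059 to 0.176.

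Across puparium formation, from -6 h to +6 h, 12 of 13 glue genes fell in the gland (adjusted p = 1.29e-06, and adjusted p = 0.213 with estimated correlation) and 10 of 10 late puff genes of 71E rose (adjusted p = 3.12e-07, and adjusted p = 0.307 with estimated correlation). Sgs5 (-10.87 ± 1.04) and Sgs7 (-10.45 ± 1.17) fell, while Eig71Ej rose by 11.33 ± 0.63 and Eig71Eh by 10.11 ± 0.77. The lysyl oxidase gene Loxl1 went from 4.16 ± 0.021 to 30783 ± 8496 scaled RPM. Changes were called for 3051 genes, 1393 higher and 1658 lower. Under median-of-ratios scaling the split was 1789 higher and 1388 lower, and the median of all genes moved from -0.079 to 0.051. With voom 1979 genes were called.

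Among genes of gland identity and glue modification, 9 of 11 members fell (adjusted p = 0.000298, and adjusted p = 0.213 with estimated correlation), with the prolyl hydroxylase gene PH4alphaSG1 at -4.76 ± 0.33, the glycosyltransferase Pgant9 at -3.87 ± 0.69, the fork head factor fkh at -3.08 ± 0.35 and the zinc finger gene sens at -3.63 ± 0.28. The separate marker list for gland tissue, which shares members with these lists, gave the same direction: 12 of 12 members fell (adjusted p = 9.46e-07, and adjusted p = 0.213 with estimated correlation). Secretory pathway genes rose at the same time, with 10 of 23 passing (adjusted p = 9.46e-07, and adjusted p = 0.333 with estimated correlation), such as the chaperones Hsc70-3 at 2.50 ± 0.23 and Gp93 at 1.99 ± 0.17. The cascade list split: 3 of 17 members rose and 9 fell, with 3 and 10 adjusted over the list alone (adjusted p = 0.153). EcR (-2.85 ± 0.14), Eip74EF (-6.13 ± 0.39), Eip75B (-2.12 ± 0.19) and Eip78C (-3.52 ± 0.44) fell. The prepupal competence factor ftz-f1 rose by 3.87 ± 0.37, the nuclear receptor Hr38 by 3.97 ± 0.29 and the late gene Eip93F by 3.07 ± 0.46. Eip63F-1 fell (-7.62 ± 0.21).

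Antimicrobial peptide genes rose in the prepupal gland: 10 of 17 members rose, with 12 adjusted over the list alone (adjusted p = 0.000188, and adjusted p = 0.47 with estimated correlation), with Dro at 4.93 ± 0.99 and the drosomycin relative Drsl6 at 12.34 ± 0.73. In the chitin and apical matrix list, 12 of 28 members rose and 4 fell, with 13 and 4 adjusted over the list alone (adjusted p = 0.0113, and adjusted p = 0.47 with estimated correlation). Timp, an inhibitor of metalloproteases, rose by 6.75 ± 0.30, and the secreted protease AdamTS-A fell (-4.68 ± 0.21), with adjusted p = 0.529 for the basement membrane and matrix remodelling list. Act5C, the cytoplasmic actin gene, and cher, which encodes filamin, changed by -3.09 ± 0.16 and -4.75 ± 0.12 in log2, and Thor by -6.33 ± 0.25. CG42537 rose by 12.06 ± 0.97. Markers of trachea, which runs along the gland, also moved: 5 of 12 members rose, with 6 adjusted over the list alone (adjusted p = 0.018, and 0.307 with estimated correlation). For cytosolic ribosomal proteins 5 of 86 fell, against 1658 of all 10172 genes (adjusted p = 0.00427, and 0.731 with estimated correlation).

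In the wing, the interval from -30 h to -6 h changed 540 genes, 312 higher and 228 lower. The ecdysone cascade list rose, while the early larval regulator chinmo fell. The repressor gene Blimp-1 rose by 7.31 ± 0.37, from 1.19 ± 0.436 to 346 ± 60.4 scaled RPM. ImpE2, an ecdysone-inducible gene of imaginal discs, rose by 7.59 ± 0.31, and chinmo changed by -4.65 ± 0.24.

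For the cascade list, 7 of 17 members rose and 1 fell (adjusted p = 9.89e-07, and adjusted p = 0.0206 with estimated correlation), with Hr4 at 5.36 ± 0.35, Eip78C at 4.74 ± 0.44 and Eip75B at 1.32 ± 0.19, while ftz-f1 fell (-2.92 ± 0.37). EcR moved by -0.89 ± 0.14 (adjusted p = 0.00113), short of 2-fold. It passed with no fold minimum and, among fits with a library left out, without WT wing -6 h replicate 1 (-1.03, adjusted p = 0.00318). Among other ecdysone-induced genes, 4 of 13 members rose (adjusted p = 0.00159, and adjusted p = 0.217 with estimated correlation), including ImpE1 (3.86 ± 0.59) and ImpE3 (4.30 ± 0.44). The timing genes went opposite ways, with chinmo falling as the let-7 microRNA cluster transcript let7C rose by 4.32 ± 0.38 and Syp, an RNA-binding regulator, by 1.32 ± 0.17. Heterochronic genes as a list gave adjusted p = 0.428. Notch and proneural genes rose: 7 of 17 members rose, with 9 adjusted over the list alone (adjusted p = 4.58e-08, and adjusted p = 0.0206 with estimated correlation), with the bristle gene sc at 1.73 ± 0.34, a call that was lost without WT wing -30 h replicate 1 (adjusted p = 0.0503). DNA replication genes shifted down as a list by a median of -0.55 (adjusted p = 1.15e-05, and adjusted p = 0.0288 with estimated correlation).

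Cuticle and matrix genes included the cuticle proteins Cpr49Ac (5.36 ± 0.55) and Cpr65Ec (4.19 ± 0.23), the chitinases Cht5 (3.17 ± 0.28) and Cht10 (2.28 ± 0.22) and the zona pellucida protein neo (2.37 ± 0.32). In the prepupal and pupal cuticle list, 3 of 14 members rose and 1 fell, with 4 and 2 adjusted over the list alone (adjusted p = 0.0179, and adjusted p = 0.31 with estimated correlation). The small heat shock genes Hsp23 (4.31 ± 0.54), Hsp27 (2.7 ± 0.42) and Hsp67Ba (4.37 ± 0.55) rose, as did Mmp2 (2.69 ± 0.45), the protease gene Sb (2.69 ± 0.37), the wing intervein factor bs (2.08 ± 0.25) and the serpin Spn100A (6.33 ± 0.41). Nplp4, a neuropeptide-like precursor, fell (-6.90 ± 0.35). Markers of other tissues moved with time as well. For fat body genes, 5 of 15 members fell, with 7 adjusted over the list alone (adjusted p = 9.58e-06, and adjusted p = 0.241 with estimated correlation), such as the lipoprotein gene apolpp (-5.20 ± 0.96) and Lsp1beta (-5.02 ± 0.79). WT wing -30 h replicate 2 carried most of this, with apolpp at 822.6 and Lsp1beta at 787 scaled RPM against 41.3 and 65.7 in replicate 1. Without it the values were -3.059 (adjusted p = 0.011) and -3.235 (adjusted p = 0.00171). The same library held the 71E gene Eig71Ea at 159.7 against 2.98. For blood cell genes, 5 of 13 members fell, with 6 adjusted over the list alone (adjusted p = 0.000162, and adjusted p = 0.276 with estimated correlation), and for muscle and myoblast genes, 1 of 14 members rose and 4 fell, with 1 and 6 adjusted over the list alone (adjusted p = 0.00926, and adjusted p = 0.326 with estimated correlation). Glue genes made up 2.38% and 1.63% of the reads of the WT wing at -6 h (95% Wilson intervals 2.37 to 2.39 and 1.63 to 1.64) against 0.0222% and 0.0789% at -30 h. These intervals cover counting error only. In this wing comparison 7 of 13 members rose and 4 fell, with 8 and 4 adjusted over the list alone (adjusted p = 0.413), with Sgs5 at 6.43 ± 1.04 and ng1 at -5.43 ± 0.46. Leaving out WT wing -6 h replicate 2 lowered the total to 333 genes, and leaving out genes within reach of gland RNA carry-over gave 485.

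From -6 h to +6 h mitosis and DNA replication genes fell in the WT wing and 12 of 28 apical matrix genes rose. Osi7, a membrane protein gene of cuticle-forming epithelia, rose by 12.72 ± 1.12 and the zona pellucida gene dyl by 10.35 ± 0.65. The cytokinesis gene tum changed by -2.77 ± 0.47 and PCNA, the replication clamp, by -2.30 ± 0.28. Of the 1694 genes that changed, 1078 rose and 616 fell.

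For mitosis, 29 of 36 members fell, with 31 adjusted over the list alone (adjusted p = 3.71e-15, and adjusted p = 0.029 with estimated correlation), sti, the citron kinase gene, at -2.66 ± 0.50. For DNA replication, 20 of 28 members fell, with 22 adjusted over the list alone (adjusted p = 4.24e-13, and adjusted p = 0.00279 with estimated correlation), Mcm5 at -2.26 ± 0.20. For ribosome biogenesis, 16 of 24 members fell (adjusted p = 2.07e-12, and adjusted p = 0.029 with estimated correlation), nop5 at -1.74 ± 0.24. Secretory genes rose in the wing too: 13 of 23 members rose (adjusted p = 2.07e-12, and adjusted p = 0.141 with estimated correlation), Hsc70-3 by 2.05 ± 0.23 and the translocon gene Sec61beta by 1.74 ± 0.28. For glycolysis, 8 of 13 members rose (adjusted p = 3.18e-06, and adjusted p = 0.112 with estimated correlation), with lactate dehydrogenase Ldh at 4.04 ± 0.35 and Pglym78 at 2.02 ± 0.32. In the cuticle list 6 of 14 members rose (adjusted p = 0.00786, and adjusted p = 0.266 with estimated correlation), including TwdlT at 6.06 ± 0.49. In the chitin and apical matrix list 12 of 28 members rose and 2 fell (adjusted p = 0.00246, and adjusted p = 0.35 with estimated correlation), with nyo at 4.78 ± 0.36, Cht5 at 3.72 ± 0.28 and the imaginal disc growth factor Idgf4 at -3.60 ± 0.20. Osi6 (11.26 ± 0.89), ect (11.45 ± 0.75), CG6118 (11.05 ± 0.62) and ImpL1 (10.84 ± 0.69) were among the largest rises of abundant genes.

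Among hormone-related genes, EcR rose by 1.67 ± 0.14, ftz-f1 by 4.92 ± 0.37, E23 by 4.05 ± 0.55 and Cyp18a1, which inactivates ecdysone, by 5.8 ± 0.38, while Blimp-1 (-2.76 ± 0.37) and the juvenile hormone target Kr-h1 (-1.43 ± 0.18) fell. For other ecdysone-induced genes, 7 of 13 members rose and 2 fell (adjusted p = 0.0341, and adjusted p = 0.266 with estimated correlation). The wing hair genes mwh and f rose by 4.67 ± 0.33 and 4.26 ± 0.29, and cher fell (-2.40 ± 0.12); the cytoskeleton list gave adjusted p = 0.0675. The proteases Sb and Np rose by 3.83 ± 0.37 and 3.90 ± 0.55. Markers of neurons and glia moved as well: 3 of 11 members rose (adjusted p = 0.00631, and adjusted p = 0.262 with estimated correlation), with the axonal cytoskeleton gene futsch at 4.55 ± 0.73; srp, a GATA factor of blood cells and fat body, rose by 3.38 ± 0.50. The glue share of wing reads, again without ng1 to ng4 and Pig1, was 0.0238% and 0.102% at +6 h. In the glue list 8 of 13 members fell, with 9 adjusted over the list alone (adjusted p = 0.000107, and adjusted p = 0.217 with estimated correlation). In the 71E list meanwhile 9 of 10 members rose, with 10 adjusted over the list alone (adjusted p = 0.000334, and adjusted p = 0.35 with estimated correlation). These 9 genes stood in wing at 0.15% to 0.223% of their gland level at +6 h, so gland RNA in the wing libraries is not excluded as their source.

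**Figure D2:**
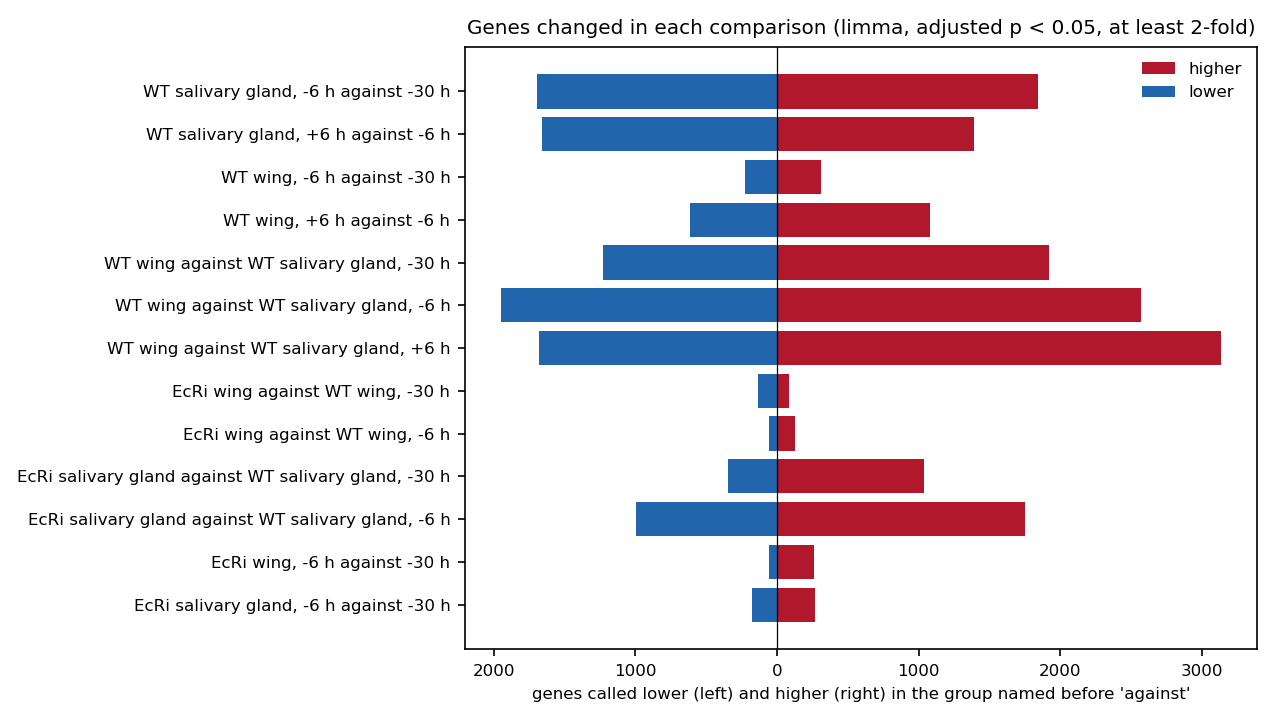
Numbers of genes called higher (right) and lower (left) in each of the 13 comparisons between groups, on a linear axis in genes. The gland changed 3535 genes from -30 h to -6 h (1055 in a fit of only the compared libraries) and the wing 540.

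The tissues were compared directly at each WT time. The wing patterning, mitosis, DNA replication and Notch lists were higher in wing, and the secretory, glue and gland identity lists lower, at all 3 times with the preset correlation. With an estimated correlation none of these 7 lists was called at +6 h (adjusted p = 0.0634 to 0.234), the glue list at none of the 3 times, DNA replication not at -30 h (adjusted p = 0.205) and the secretory list not at -6 h (adjusted p = 0.129). At -30 h 3147 genes differed (1918 higher in wing, 1229 lower), at -6 h 4521 (2572 and 1949) and at +6 h 4817 (3135 and 1682). Leaving out WT gland -30 h replicate 1, which leaves the gland group with the library of few detected genes, raised the -30 h count to 4786; only the compared libraries gave 785 and array weights 1560. Median-of-ratios scaling changed the +6 h split to 2661 higher and 2203 lower, and the median of all genes from 0.297 to 0.045.

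At -30 h, among wing patterning genes 31 of 37 members were higher and 1 was lower, with 33 and 1 adjusted over the list alone (adjusted p = 5.29e-14, and adjusted p = 0.0157 with estimated correlation), such as rn (6.85 ± 0.61), the POU gene nub (6.05 ± 0.56) and the dorsal selector ap (6.04 ± 0.63). For mitosis, 34 of 36 members were higher (adjusted p = 9.33e-17, and adjusted p = 0.019 with estimated correlation), with the phosphatase gene stg at 6.78 ± 0.67, sti at 5.88 ± 0.50 and the kinase gene polo at 5.79 ± 0.62. Without WT gland -30 h replicate 2 these were 5.413 (rn), 4.748 (nub), 4.618 (ap), 5.22 (stg), 4.76 (sti) and 4.541 (polo). All secretory genes tested were lower in wing, 23 of 23 (adjusted p = 7.19e-20, and adjusted p = 0.0347 with estimated correlation), such as TRAM (-3.44 ± 0.17), Hsc70-3 (-3.35 ± 0.23) and Pdi (-2.93 ± 0.24). For gland identity genes, 10 of 11 members were lower (adjusted p = 4.07e-09, and adjusted p = 0.0157 with estimated correlation), with PH4alphaSG1 at -5.52 ± 0.33, the bHLH gene sage at -5.16 ± 0.36 and fkh at -4.91 ± 0.35. In the glue list 9 of 13 members were lower (adjusted p = 9.26e-06, and adjusted p = 0.129 with estimated correlation), ng3 by -6.16 ± 0.50 and ng1 by -6.04 ± 0.46. Notch genes were higher in wing, 11 of 17 (adjusted p = 5.55e-05, and adjusted p = 0.0347 with estimated correlation), E(spl)m2-BFM at 4.17 ± 0.35. The death activators rpr (4.95 ± 0.38) and hid (3.99 ± 0.25) and the apical matrix gene dpy (4.25 ± 0.24) were also higher in wing. Cell type markers differed: tracheal genes were higher in wing, 10 of 12 (adjusted p = 3.71e-05, and adjusted p = 0.0347 with estimated correlation), with uif at 6.49 ± 0.78 (4.53 without that library); the myoblast gene twi differed by 4.13 ± 0.36; fat body genes were lower in wing, 6 of 15 (adjusted p = 0.00508, and adjusted p = 0.381 with estimated correlation), Lsp1alpha by -3.37 ± 0.71, or -1.944 without WT wing -30 h replicate 1. Eip63F-1 (-3.94 ± 0.21), GstD2 (-5.65 ± 0.39), Thor (-4.32 ± 0.25) and CG11300 (-6.81 ± 0.45) were higher in gland, and EcR did not differ detectably (0.19 ± 0.14, adjusted p = 0.309).

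At -6 h the wing had less EcR (-2.86 ± 0.14) and lower cascade expression: 1 of 17 members was higher and 9 were lower, with 1 and 10 adjusted over the list alone (adjusted p = 0.00827, and adjusted p = 0.113 with estimated correlation). Eip74EF (-3.83 ± 0.39), Eip78C (-3.82 ± 0.44) and Eip75B (-2.41 ± 0.19) were lower in wing and Blimp-1 was higher (5.16 ± 0.37). ImpE2 (5.92 ± 0.31) and ImpE1 (5.34 ± 0.59) were higher in wing, whereas Eip63F-1 was lower (-7.67 ± 0.21). DNA replication genes, with 25 of 28 higher in wing (adjusted p = 2.37e-07, and adjusted p = 0.0168 with estimated correlation), included Mcm2 (3.46 ± 0.30). Mitosis genes, with 33 of 36 (adjusted p = 6.64e-11, and adjusted p = 0.0318 with estimated correlation), included Incenp (5.39 ± 0.27) and CycB (4.99 ± 0.27). For ribosome biogenesis 21 of 24 members were higher (adjusted p = 1.04e-08, and adjusted p = 0.0324 with estimated correlation), Fib by 4.35 ± 0.30 and Nop60B by 4.12 ± 0.16, and for mitochondrial ribosomal proteins 47 of 71 members were higher, with 49 adjusted over the list alone (adjusted p = 4.08e-06, and adjusted p = 0.0168 with estimated correlation), mRpL39 by 3.08 ± 0.26. Wing patterning (32 of 37 higher and 1 lower, adjusted p = 6.64e-11, and adjusted p = 0.0168 with estimated correlation) included Dll (6.06 ± 0.45), mirr (5.75 ± 0.55) and salm (5.71 ± 0.35). The Notch and proneural list (15 of 17, adjusted p = 1.21e-06, and adjusted p = 0.0169 with estimated correlation) included sc (4.8 ± 0.34), and the cadherin gene ds differed by 5.08 ± 0.27. Glue genes (12 of 13 lower, adjusted p = 1.48e-06, and adjusted p = 0.0991 with estimated correlation) stayed far below the gland, Sgs7 by -8.94 ± 1.17, as did sage (-7.30 ± 0.36) and fkh (-7.23 ± 0.35). Autophagy genes (8 of 19 lower, adjusted p = 0.00164, and adjusted p = 0.122 with estimated correlation) included Atg8a (-2.43 ± 0.18), and Buffy (-6.03 ± 0.30), Xbp1 (-2.44 ± 0.15) and Thor (-7.99 ± 0.25) were lower in wing. Fat body genes were mostly lower in wing (11 of 15 lower and 3 higher, adjusted p = 0.0025, and adjusted p = 0.374 with estimated correlation), with Lsp2 at -7.77 ± 0.88 and Fbp1 at -7.70 ± 0.76.

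At +6 h, in the cuticle list 9 of 14 members were higher (adjusted p = 0.00521, and adjusted p = 0.193 with estimated correlation), TwdlT by 5.47 ± 0.49 and TwdlE by 5.19 ± 0.44, and dyl (5.51 ± 0.65), nyo (5.22 ± 0.36) and dpy (5.05 ± 0.24) were higher in wing. The chitin and apical matrix list as a whole gave 17 higher and 5 lower of 28 (adjusted p = 0.0635). For cytoskeleton and morphogenesis genes, 23 of 36 members were higher and 2 were lower (adjusted p = 0.00352, and adjusted p = 0.0634 with estimated correlation), f by 4.98 ± 0.29. Sb (5.22 ± 0.37), Np (4.55 ± 0.55) and Ldh (3.34 ± 0.35) were higher in wing, whereas Loxl1 (-8.72 ± 0.85) and Timp (-7.30 ± 0.30), both basement membrane or matrix genes, were higher in gland; that list gave adjusted p = 0.33. EcR was now higher in wing (1.66 ± 0.14), as were Eip74EF (1.91 ± 0.39), E23 (2.84 ± 0.55) and ImpE1 (5.09 ± 0.59), while Hr38 was lower (-4.42 ± 0.29). The 71E genes (10 of 10 lower in wing, adjusted p = 1.31e-06, and adjusted p = 0.188 with estimated correlation) included Eig71Ef (-9.47 ± 1.14) and Eig71Eg (-9.43 ± 1.23). Antimicrobial peptide genes (14 of 17 lower, adjusted p = 1.79e-05, and adjusted p = 0.279 with estimated correlation) went the same way, as did Pdi (-2.61 ± 0.24), sage (-6.57 ± 0.36) and fkh (-4.83 ± 0.35). Wing patterning genes (32 of 37 higher and 1 lower, adjusted p = 1.23e-07, and adjusted p = 0.0634 with estimated correlation) included bi (5.07 ± 0.34) and rn (5.04 ± 0.61). Mitosis genes were higher in wing (31 of 36, adjusted p = 5.96e-05, and adjusted p = 0.164 with estimated correlation), Incenp by 3.94 ± 0.27 and CycB by 3.53 ± 0.27, as did E(spl)m2-BFM (4.60 ± 0.35). The separate wing marker list was higher in wing (11 of 12 higher and 1 lower, adjusted p = 0.00275, and adjusted p = 0.0634 with estimated correlation).

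In EcRi wings 224 genes differed from WT at -30 h, 87 higher and 137 lower. Like w, the near-identical heat shock genes Hsp70Ba and Hsp70Bb rose in every EcRi group, here by 4.95 ± 0.34 and 4.97 ± 0.47. Their reads cannot be assigned with certainty, and line differences are not excluded. ImpE2 was higher by 2.16 ± 0.31, and gland-type genes such as ng1 (-3.47 ± 0.46) and ng3 (-3.83 ± 0.50) were lower.

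Of the cascade list only Eip78C passed (2.19 ± 0.44; list adjusted p = 0.962, with a median of -0.011, a mean of 0.043 and an upward test), and not in 3 of the fits with a library left out (adjusted p = 0.0921 to 0.125). The same held for chinmo, which differed by -1.35 ± 0.24 (adjusted p = 0.0593 to 0.0775). For both genes the libraries were WT wing -30 h replicate 1 and EcRi wing -30 h replicates 1 and 2. In the heat shock list 5 of 27 members rose, with 6 and 1 adjusted over the list alone (adjusted p = 0.000203, and 0.275 with estimated correlation), and the stress gene Gadd45 rose by 2.01 ± 0.23. In the glue list 4 of 13 members fell (adjusted p = 0.000143, and 0.317 with estimated correlation), and fkh (-2.54 ± 0.35) and PH4alphaSG1 (-2.67 ± 0.33) fell. For fat body markers, 2 of 15 members fell, with 7 adjusted over the list alone (adjusted p = 1.27e-06, and adjusted p = 0.275 with estimated correlation), but as given above WT wing -30 h replicate 2 stood far above replicate 1 for apolpp and Lsp1beta, which were at most 23.7 and 35.2 in EcRi libraries. CG3097 (3.72 ± 0.36) and CG32074 (4.10 ± 0.56) rose, and CG13560 (-4.75 ± 0.45), CG32198 (-4.14 ± 0.55) and CG43117 (-3.75 ± 0.37) fell. In WT wing at -30 h ng1 and ng3 stood at 1.68% and 1.51% of their WT gland level, fkh and PH4alphaSG1 at 2.96% and 2.12%, and CG13560, CG32198 and CG43117 at 1.63%, 1.18% and 1.07%. In EcRi wing CG32074 stood at 0.121% of its EcRi gland level. Gland RNA in the wing libraries is therefore not excluded as the source of these calls. The count fell to 97 without EcRi wing -30 h replicate 1 and 98 without replicate 2, and rose to 361 without WT gland -30 h replicate 2, which shares the estimate of spread. It was 396 with wing libraries only, 432 with array weights and 123 with a pseudocount of 4.

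At -6 h 181 genes changed, 125 higher and 56 lower in EcRi wings. Those higher included 6 genes of the cuticle list, TwdlT by 4.20 ± 0.49, from 2.42 ± 0.288 to 62.3 ± 11.8 scaled RPM, and Edg78E by 3.38 ± 0.29. Hsp70Ba and Hsp70Bb rose again (8.36 ± 0.34 and 8.72 ± 0.47). Of the cascade 1 of 17 rose and 2 fell (adjusted p = 0.135).

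In the cuticle list 6 of 14 members rose and 1 fell (adjusted p = 3.62e-09, and adjusted p = 0.0877 with estimated correlation), Cpr49Ah by 2.75 ± 0.37. In the chitin and apical matrix list 4 of 28 members rose, with 5 adjusted over the list alone (adjusted p = 0.00378, and adjusted p = 0.573 with estimated correlation), with mey at 2.06 ± 0.27 and mmy, which makes the chitin precursor, at 1.87 ± 0.15. Gadd45 (1.74 ± 0.23), CHKov1 (6.38 ± 0.21) and CG6118 (4.32 ± 0.62) rose, and the glutathione transferase GstE1 fell (-2.81 ± 0.40). A group of calls depended on single libraries. Blimp-1 (-1.87 ± 0.37; adjusted p = 0.0758 to 0.181 when lost) and Eip75B (-1.02 ± 0.19; 0.0683 to 0.0966) were lower in EcRi. The genes ftz-f1 (1.93 ± 0.37; 0.138 to 0.146), chinmo (1.18 ± 0.24; 0.104 to 0.162), Osi7 (5.24 ± 1.12; 0.137 to 0.323) and dyl (3.66 ± 0.65; 0.0616 to 0.121) were higher. Blimp-1 and chinmo were lost without any 1 of the 4 libraries compared, and Eip75B without all but EcRi wing -6 h replicate 2. Osi7 and dyl were lost without all but EcRi wing -6 h replicate 1, and ftz-f1 without replicate 2 of either genotype. The share of glue reads, without ng1 to ng4 and Pig1, was 0.017% and 0.0133% in EcRi wings at -6 h. In the glue list 1 of 13 members rose and 7 fell, with 2 and 8 adjusted over the list alone (adjusted p = 3.52e-07, and adjusted p = 0.215 with estimated correlation). Sgs4 changed by -7.03 ± 0.64 and Sgs5 by -6.78 ± 1.04, and Eip63F-1, abundant in gland, fell with them (-1.87 ± 0.21). The total was 156 without genes within reach of gland carry-over by WT levels. With wing libraries only it was 306, and with array weights 345.

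In the gland the same comparison at -30 h gave 1385 genes, 1041 higher and 344 lower in the libraries labelled EcRi. The EcR level did not differ detectably there, and a difference in stage is not excluded. A fit of only the compared libraries gave 15 genes, array weights 130, gland libraries only 439 and no fold minimum 2106, with 900 at a pseudocount of 4. CG32074, a gene of unknown function, went from 45 ± 5.8 to 169049.8 ± 55365 scaled RPM (11.81 ± 0.56). Hr4 rose by 5.40 ± 0.35 and the glue gene Sgs1 by 5.55 ± 1.05 (3.671 without WT gland -30 h replicate 1), while the broad-complex gene br fell (-2.32 ± 0.49).

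For DNA replication, 13 of 28 members fell, with 15 adjusted over the list alone (adjusted p = 1.04e-08, and adjusted p = 0.0126 with estimated correlation), with CycE at -1.70 ± 0.23 and PCNA at -1.47 ± 0.28. In the cascade list 4 of 17 members rose and 3 fell, with 5 and 3 adjusted over the list alone (adjusted p = 0.401): Eip78C (2.69 ± 0.44) and Hr38 (1.94 ± 0.29) rose with Hr4, and vri fell (-2.41 ± 0.46) with br. ImpE2, of another list, rose by 3.01 ± 0.31. The br call was lost without WT gland -30 h replicate 2 (adjusted p = 0.0607). Without EcRi gland -30 h replicate 1 br was -3.489, and without replicate 2 br was -1.142 and vri -1.52. In the chitin and apical matrix list 10 of 28 members rose and 2 fell, with 11 and 2 adjusted over the list alone (adjusted p = 0.0053, and adjusted p = 0.682 with estimated correlation), with the BMP regulator cv-2 at 4.33 ± 0.61 and Idgf1 at 2.26 ± 0.43, which were 2.871 and 1.466 without WT gland -30 h replicate 2. The cytolinker gene shot rose by 2.08 ± 0.11 and the planar polarity cadherin stan fell (-3.54 ± 0.15). In the heat shock list 11 of 27 members rose and 1 fell (adjusted p = 0.0313, and 0.682 with estimated correlation), with Hsp70Ba at 4.56 ± 0.34 and Hsp70Bb at 4.96 ± 0.47. In the cell death list 5 of 10 members rose (adjusted p = 0.0175, and 0.682 with estimated correlation). Thor rose by 2.09 ± 0.25, the cytokine gene upd3 by 3.71 ± 0.28, Ldh by 2.33 ± 0.35 and ng4 by 4.84 ± 0.34. Other large rises were CG13445 (11.24 ± 0.69), CG14143 (10.33 ± 0.69), CG34273 (10.02 ± 0.57), CG33267 (8.87 ± 1.43, and 5.61 without WT gland -30 h replicate 2) and CG32071 (8.54 ± 0.40), and large falls were the lysozyme gene LysP (-7.08 ± 0.37), CG14850 (-7.48 ± 0.97) and CG8087 (-6.42 ± 1.04). Markers of fat body (5 of 15 members rose, with 7 and 1 adjusted over the list alone; adjusted p = 0.0342, and adjusted p = 0.724 with estimated correlation), blood cells (6 of 13 members rose, with 7 adjusted over the list alone; adjusted p = 0.0175, and adjusted p = 0.682 with estimated correlation) and muscle (4 of 14 members rose, with 6 adjusted over the list alone; adjusted p = 0.0313, and adjusted p = 0.682 with estimated correlation) were higher in the same libraries, Fbp1 by 5.29 ± 0.76. Leaving out WT gland -30 h replicate 2 gave 912 genes (624 higher and 288 lower), leaving out its replicate 1 gave 4014, and leaving out EcRi gland -30 h replicate 2 gave 647. Of the calls, 688 were shared with the fit without WT gland -30 h replicate 2.

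At -6 h the EcRi gland differed from WT in 2743 genes, 1750 higher and 993 lower. Ecdysone-cascade genes and 8 of 13 glue genes were lower, and genes for ribosome production and DNA replication were higher. Sgs3 was at 4289 ± 3984 scaled RPM against 2179193 ± 543710.5 in WT (-9.37 ± 1.32), and Eip74EF changed by -5.08 ± 0.39. Fib rose by 3.35 ± 0.30 and Nop60B by 3.04 ± 0.16.

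In the cascade list 2 of 17 members rose and 11 fell (adjusted p = 5.62e-05, and adjusted p = 0.0354 with estimated correlation). Eip78C (-5.70 ± 0.44), Eip75B (-3.50 ± 0.19), E23 (-3.08 ± 0.55), vri (-3.07 ± 0.46), the nuclear receptor Hr78 (-2.65 ± 0.27) and br (-1.91 ± 0.49) fell, while ftz-f1 (2.23 ± 0.37) and Hr38 (1.66 ± 0.29) rose. Glue genes split: 5 of 13 members rose and 8 fell (adjusted p = 0.136). Sgs5 (-10.12 ± 1.04) and Sgs8 (-10.09 ± 1.21) fell with Sgs3. The 5 that rose, named after their values were seen, were ng1 (5.0 ± 0.46), ng2 (4.34 ± 0.43), ng3 (3.05 ± 0.50), Pig1 (1.27 ± 0.40) and ng4, which was at 0 reads in both WT libraries and at 18.6 ± 10.6 scaled RPM in EcRi. The Pig1 call was lost in 3 fits with a library left out (adjusted p = 0.0543 to 0.194), those without WT gland -6 h replicate 1 or 2 or EcRi gland -6 h replicate 1. In the 71E list 1 of 10 members rose and 7 fell, with 1 and 8 adjusted over the list alone (adjusted p = 0.0167, and adjusted p = 0.808 with estimated correlation). For ribosome biogenesis 19 of 24 members rose, with 20 adjusted over the list alone (adjusted p = 4.31e-10, and adjusted p = 0.0354 with estimated correlation). For mitochondrial ribosomal proteins 37 of 71 members rose, with 42 adjusted over the list alone (adjusted p = 7.24e-07, and adjusted p = 0.0168 with estimated correlation), mRpL39 by 2.62 ± 0.26. For DNA replication 21 of 28 members rose, with 24 adjusted over the list alone (adjusted p = 1.25e-05, and adjusted p = 0.0354 with estimated correlation), CycE by 1.87 ± 0.23 and dpa by 1.81 ± 0.17.

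Autophagy genes (1 of 19 members rose and 8 fell, adjusted p = 0.00417, and adjusted p = 0.308 with estimated correlation) were lower in EcRi. So were Buffy (-4.75 ± 0.30), rpr (-2.44 ± 0.38) and hid (-1.91 ± 0.25), members of the cell death list. Of gland identity genes, sage (-2.75 ± 0.36) and Pgant9 (-3.41 ± 0.69) fell and PH4alphaSG2 rose by 5.59 ± 0.32; the list gave a median of 0.03, a mean of -0.15 and a downward test (adjusted p = 0.515). The timing gene chinmo rose by 2.06 ± 0.24 and let7C fell (-2.93 ± 0.38). GstD2 (7.0 ± 0.39) and the glycerol phosphate dehydrogenase gene Gpdh1 (3.10 ± 0.25) rose, and Ldh fell (-2.51 ± 0.35). The apical protein gene pio (3.92 ± 0.19), Idgf3 (3.22 ± 0.31), cv-2 (4.17 ± 0.61) and the collagen gene Col4a1 (3.65 ± 0.39) rose. The chitin deacetylase Cda5 (-4.23 ± 0.37) and Mmp2 (-3.06 ± 0.45) fell. Hsp70Ba (5.99 ± 0.34) and Hsp70Bb (5.19 ± 0.47), CG42759 (9.61 ± 0.62) and CG13445 (8.97 ± 0.69) rose, and PGRP-SB2 fell (-9.63 ± 0.93). Median-of-ratios scaling moved the median of all genes from 0.155 to 0.036 and gave 1430 higher and 1230 lower genes.

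**Figure D3:**
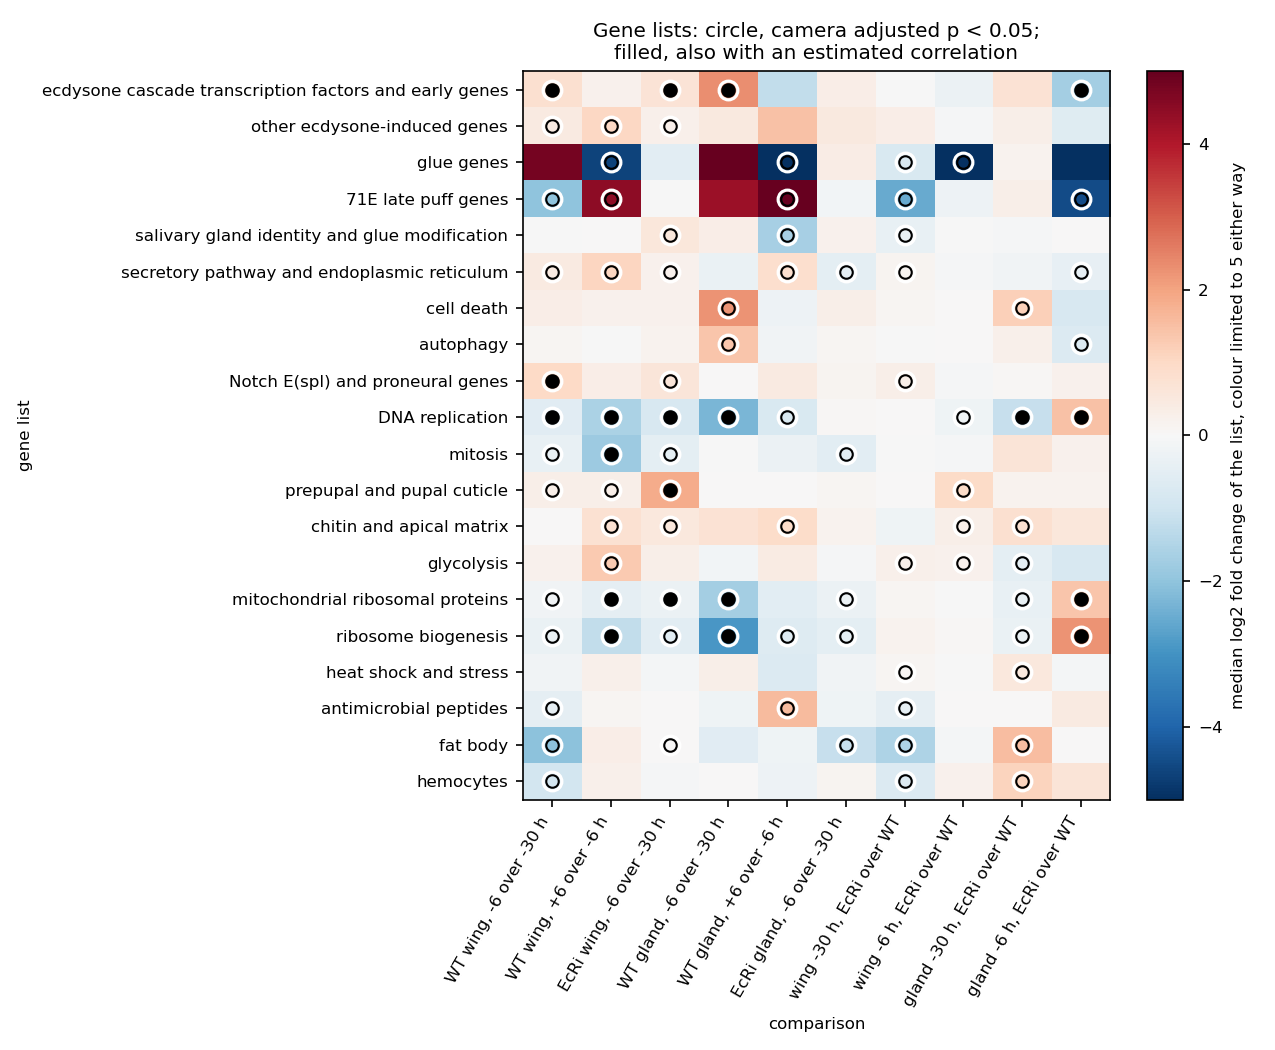
Median log2 fold change of 20 gene lists (rows) in 10 comparisons (columns), with colour limited to 5 either way; circles mark camera adjusted p under 0.05 and filled circles the same with estimated correlation. Ribosome biogenesis has a median of -2.91 in the WT gland from -30 h to -6 h and of 2.26 in the EcRi gland against WT at -6 h.

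Within EcRi tissue, the gland changed 448 genes from -30 h to -6 h, 270 higher and 178 lower. The EcRi wing changed 315 genes, 260 higher and 55 lower. In the EcRi wing Blimp-1 rose by 5.63 ± 0.37, Hr4 by 5.53 ± 0.35, ImpE2 by 4.31 ± 0.31 and ImpE3 by 3.16 ± 0.44, chinmo fell (-2.12 ± 0.24) and let7C rose by 3.04 ± 0.38. In the EcRi gland Blimp-1 rose by 2.33 ± 0.37, and EcR moved by -0.42 ± 0.14 (adjusted p = 0.11).

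In the EcRi wing cascade list 5 of 17 members rose, with 7 adjusted over the list alone (adjusted p = 1.3e-06, and adjusted p = 0.0124 with estimated correlation), and 2 in the EcRi gland (adjusted p = 0.268). In the EcRi wing cuticle list 8 of 14 members rose, with 9 adjusted over the list alone (adjusted p = 7.94e-12, and adjusted p = 0.0124 with estimated correlation), TwdlT by 5.83 ± 0.49, and Cht5 rose by 2.80 ± 0.28. DNA replication genes shifted down in the EcRi wing by a median of -0.79, with 1 of 28 passing and 2 adjusted over the list alone (adjusted p = 7.91e-13, and adjusted p = 0.00276 with estimated correlation). EcR moved by -0.66 ± 0.14 in the EcRi wing (adjusted p = 0.0162), short of 2-fold. Spn100A (5.46 ± 0.41) and the translation factor eEF1alpha2 (5.07 ± 0.37) rose, and Nplp4 (-5.32 ± 0.35) and Vajk3 (-4.65 ± 0.32) fell. In the EcRi gland the chitinases Cht5 (2.30 ± 0.28) and Cht6 (2.67 ± 0.31), Timp (2.63 ± 0.30), tropomyosin Tm1 (1.62 ± 0.14), Drsl5 (4.61 ± 0.36) and CG34296 (5.71 ± 0.38) rose, and vkg (-3.89 ± 0.35), Act57B (-2.57 ± 0.31) and CG13067 (-6.56 ± 0.53) fell. Fat body markers fell with them (1 of 15 members rose and 4 fell, with 1 and 7 adjusted over the list alone; adjusted p = 0.000603, and adjusted p = 0.51 with estimated correlation). The EcRi wing count was 173 without EcRi wing -30 h replicate 1, 169 without its replicate 2 and 151 without EcRi wing -6 h replicate 2. The EcRi gland count was 295 without EcRi gland -30 h replicate 2, 230 without EcRi gland -6 h replicate 2 and 689 without WT gland -30 h replicate 2. With libraries of the tissue only the counts were 476 in wing and 143 in gland, with array weights 492 in wing, and with no fold minimum 762 in gland.

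Temporal changes of WT and EcRi were then set side by side. Across the 10172 genes, which are not independent replicates, the changes from -30 h to -6 h in WT and EcRi correlated with Pearson r = 0.599 (Spearman rho = 0.575) in wing and 0.312 (0.296) in gland. Of the 540 genes that changed in WT wing, 489 (90.6%) moved in the same direction in EcRi wing and 193 of them passed there. Of the 3535 in WT gland, 2439 (69.0%) moved in the same direction in EcRi gland and 205 of them passed. The slope of EcRi on WT changes over these genes was 0.472 in wing and 0.121 in gland. Without EcRi wing -30 h replicate 1 or 2, or EcRi wing -6 h replicate 2, the wing number was 111, 114 and 97. Without WT gland -30 h replicate 1 or 2, EcRi gland -30 h replicate 2, or EcRi gland -6 h replicate 2, the gland number was 319, 321, 136 and 113. With libraries of the tissue only the numbers were 303 and 83, with only the compared libraries 73 in gland, with array weights 307 in wing, and with no fold minimum 394 in gland.

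**Figure D4:**
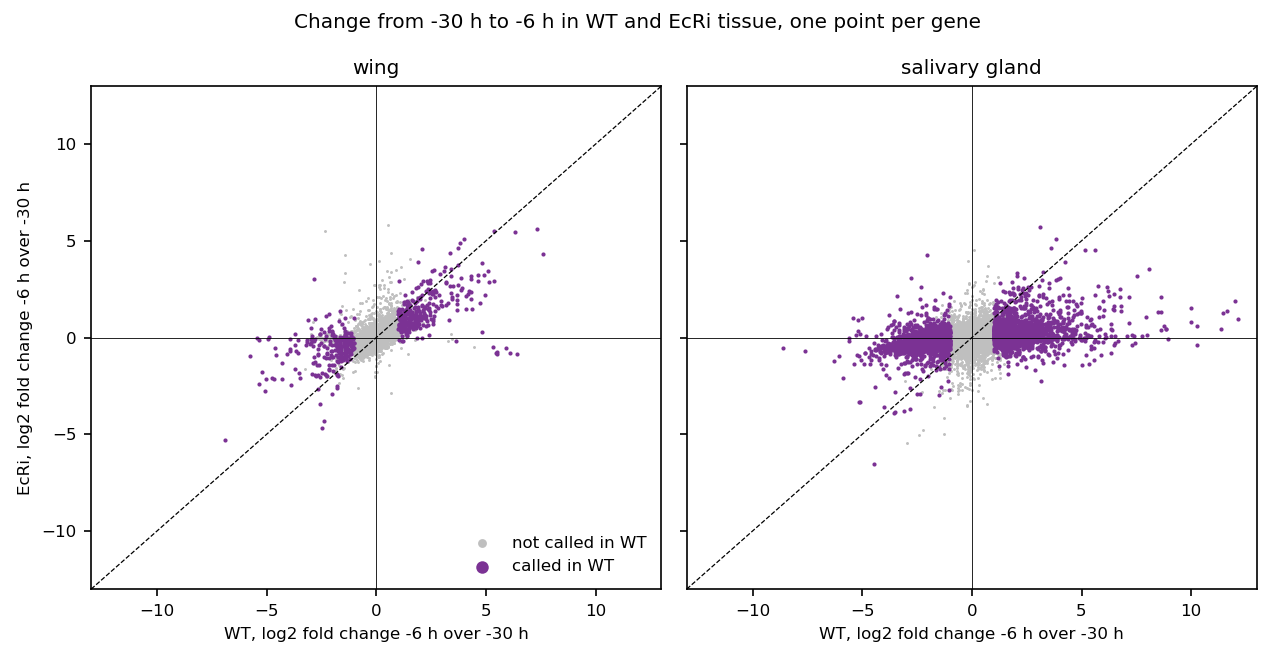
Log2 fold change from -30 h to -6 h in WT (horizontal axis) and EcRi (vertical axis), one point per gene, for wing and salivary gland, with genes called in WT in purple and the dashed line marking equal change. The slope over called genes is 0.472 in wing and 0.121 in gland.

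Differences between these changes were tested directly as interactions in the same limma fit. In the gland the change from -30 h to -6 h differed between EcRi and WT for the cascade list, where 10 of 17 members had a lower change in EcRi (adjusted p = 0.000155, and adjusted p = 0.043 with estimated correlation). Ribosome biogenesis (18 of 24, with 19 adjusted over the list alone; adjusted p = 2.09e-11, and adjusted p = 0.0323 with estimated correlation) and DNA replication genes (20 of 28, with 21 adjusted over the list alone; adjusted p = 1.32e-10, and adjusted p = 0.00331 with estimated correlation) had a higher change in EcRi. The effect of EcR-RNAi at -6 h was higher in wing than in gland for 8 cascade genes and lower for 2, with 10 and 2 adjusted over the list alone (adjusted p = 0.000297, and adjusted p = 0.0527 with estimated correlation). At -30 h DNA replication was the list with the smallest p that kept its call, with 7 of 28 higher and 13 adjusted over the list alone (adjusted p = 3.6e-08, and adjusted p = 0.016 with estimated correlation). In the wing, where 88 genes differed, cuticle genes had 2 higher and 1 lower of 14, with 5 and 2 adjusted over the list alone (adjusted p = 8.42e-05, and adjusted p = 0.212 with estimated correlation). Between WT tissues, the change up to -6 h was higher in wing than in gland for 18 of 24 ribosome biogenesis genes (adjusted p = 1.16e-11, and adjusted p = 0.0302 with estimated correlation) and the change up to +6 h was lower in wing for 19 of 36 mitosis genes and higher for 1, with 26 and 1 adjusted over the list alone (adjusted p = 3.13e-06, and adjusted p = 0.369 with estimated correlation).

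The responses to EcR-RNAi in wing and gland were then compared, although the EcR level was not lower in EcRi gland at -30 h. At -30 h 25 genes were higher in both tissues, where 8.90 would be shared by independent lists of this size, and 25 were lower in both (4.63), while 3 were higher in wing and lower in gland and 18 the reverse. These include the gland genes CG13560, CG32198 and CG43117 (lower) and CG32074, and CG13445, CG14143 and CG34273 (higher), which stood in EcRi wing at 0.0787%, 0.0982% and 0.122% of their EcRi gland level. At -6 h 33 were higher in both (21.5 for independent lists) and 32 lower in both (5.47). Of the lower, 14 lay within reach of gland carry-over. Another 7 were higher in wing and lower in gland and 2 the reverse. Across genes, which are not independent replicates, the responses correlated with r = 0.096 at -30 h and 0.281 at -6 h. The lower genes of -6 h included Eip75B, Eip63F-1, Thor, Dcr-2 and the glue genes Sgs1, Sgs3, Sgs4, Sgs5, Sgs7 and Sgs8, whose wing reads follow the glue share given above. The higher genes included w, Hsp70Ba, Hsp70Bb, chinmo, ftz-f1, mmy, CHKov1 and ng1. At -6 h Thor and Eip63F-1 stood in WT wing at 0.371% and 0.413% of their gland level, and ng1 in EcRi wing at 0.167%, so gland RNA is not excluded for them either. The -30 h overlap of 50 genes was 29 and 30 without WT wing -30 h replicate 1 and 2, 25 and 23 without EcRi wing -30 h replicate 1 and 2, and 97 and 80 without WT gland -30 h replicate 1 and 2. The -6 h overlap of 65 genes was 37 and 34 without WT wing -6 h replicate 1 and 2, and 40 and 37 without EcRi wing -6 h replicate 1 and 2. Only the compared libraries gave 9 at -30 h, array weights gave 15 and 123, and 29 and 38 were shared with a pseudocount of 4. None of these overlaps was tested.

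The authors' deposited tables of DESeq2 results allow the same counts, at an adjusted p under 0.05 and at least 2-fold. The authors' deposited tables list 3449 and 2675 genes for the WT gland intervals and 760 and 1636 for the WT wing. For EcRi against WT, the authors' deposited tables list 436 and 245 genes in wing and 1156 and 2357 in gland at -30 and -6 h. Of those in the authors' deposited tables, 196, 149, 845 and 2112 were also called here in the same direction.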

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

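The tests of differences between groups below were planned, and all tests of explanations were chosen after the results were seen. Each gene is given with the difference between changes in log2 ± standard error.

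Results in this paragraph stand out because the effect of time, tissue or RNAi differed between groups in a direct limma test. Between genotypes, the change from -30 h to -6 h differed for 2711 genes in gland and 88 in wing. In gland the EcRi change was lower than the WT change for EcR (-2.57 ± 0.20), Eip75B (-4.22 ± 0.26), Hr4 (-7.12 ± 0.49), Eip78C (-8.38 ± 0.62) and Sgs3 (-11.19 ± 1.87). In wing it was higher for CG6118 (5.85 ± 0.88), TwdlT (5.32 ± 0.70) and chinmo (2.53 ± 0.35) and lower for ImpE2 (-3.28 ± 0.43). The gland count was 4755 without WT gland -30 h replicate 1, and median-of-ratios scaling turned its split from 1457 higher and 1254 lower to 1193 and 1560. The wing count was 38 and 41 without WT wing -6 h replicate 1 and 2, 34 and 42 without EcRi wing -30 h replicate 1 and 2, 48 without EcRi wing -6 h replicate 2 and 192 without WT gland -30 h replicate 2. The gland and wing counts were 1579 and 286 with libraries of the tissue only, 1287 and 223 with only the compared libraries and 1269 and 379 with array weights; voom gave 11 and log2(RPKM + 0.1) 49 in wing.

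Between tissues, the effect of EcR-RNAi differed for 810 genes at -30 h, where the EcR level was not lower in EcRi gland, and 2207 at -6 h. At -30 h the wing effect was higher than the gland effect for LysP (4.44 ± 0.52) and CHKov1 (4.09 ± 0.30) and lower for Hr4 (-5.88 ± 0.49) and CG32071 (-8.05 ± 0.56). At -6 h it was higher (a smaller decrease) for EcR (2.08 ± 0.20), Eip75B (2.48 ± 0.26), Eip74EF (4.19 ± 0.54) and Eip78C (4.92 ± 0.62). The -30 h count was 520 without WT wing -30 h replicate 2, 440 and 431 without EcRi wing -30 h replicate 1 and 2, 4107 without WT gland -30 h replicate 1 and 497 without EcRi gland -30 h replicate 2. The -6 h split of 852 higher and 1355 lower became 1046 and 1099 under median-of-ratios scaling. Only the compared libraries gave 107 at -30 h, array weights 149, and voom 1262 at -6 h.

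Between WT tissues, the change differed for 2910 genes up to -6 h and 2749 from there to +6 h. Up to -6 h the wing change was higher for ImpE2 (7.34 ± 0.43) and Blimp-1 (4.85 ± 0.53) and lower for EcR (-3.05 ± 0.20), chinmo (-3.07 ± 0.35) and rpr (-6.38 ± 0.54). Up to +6 h it was higher for Ldh (7.15 ± 0.49), dyl (6.92 ± 0.91), Eip74EF (5.74 ± 0.54) and EcR (4.52 ± 0.20) and lower for Loxl1 (-8.21 ± 1.20) and Timp (-6.13 ± 0.43). The earlier count was 4914 without WT gland -30 h replicate 1, and its split of 1530 and 1380 became 1210 and 1775 under median-of-ratios scaling. The later split of 1713 and 1036 became 1389 and 1370 when scaled without glue and 71E genes. Only the compared libraries gave 1635 up to -6 h, array weights 1481, and voom 1433 up to +6 h.

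Glue transcripts other than those of ng1 to ng4 and Pig1 took 2.38% and 1.63% of reads in the WT wing at -6 h. The 8 abundant glue genes had a median wing to gland ratio of 0.00315 (range 0.00203 to 0.00418), and 7 gland genes outside the glue and 71E lists that the wing lacked at -30 h had 0.00304, a quotient of 0.963. Activation of the glue genes alone in wing cells is argued against, since those 7 genes were also higher in WT than in EcRi wing, by a median of 3.78 in log2 (2.16 to 6.30). Gland RNA carried into the wing libraries may therefore be the source, and EcRi wings could not show it in the same way because EcRi glands made little glue. Of the genes called lower and higher in EcRi wing at -6 h, 15 and 10 lay within reach of such carry-over.

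Replicate 2 of the WT gland at -30 h showed 6354 genes against 10996 in replicate 1. Fewer reads are argued against, as it held 0.964 times the reads of replicate 1. Of 2193 genes at 2 to 10 scaled RPM in the EcRi gland at -6 h, 44.8% had 0 reads in replicate 2, 1.09% in replicate 1 and at most 4.2% in any library but replicate 2, yet their summed level was 0.968 times that of replicate 1. Lower expression of these genes would lower that sum, so few starting RNA molecules may explain the library, and no biological explanation was tested beyond this. Of the genes called higher in EcRi gland at -30 h, 52.2% had 0 reads in that library, against 37.7% of all genes tested, and without it 68.4% of calls were higher in place of 75.2%.

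In EcRi wings at -6 h, 125 genes were higher than in WT, 6 of them in the cuticle list of 14, whose call was lost with estimated correlation (adjusted p = 0.0877). A shift of the whole wing programme to a later stage is argued against: the 1019 genes lower in WT wing at +6 h than at -30 h (median -1.64) had a median of -0.044 in EcRi against WT wing (quartiles -0.215 and 0.121), though a shift limited to genes that change soonest stays open. Of the 125, 63 were higher in WT wing at +6 h than at -30 h, against 18.2 for independent lists. Such a limited shift, early activation of some prepupal wing genes or genetic background could each give this overlap. General activation is not borne out: all 1485 genes higher in WT wing at +6 h had a median of 0.055. Of the 63, the change over time was called higher in EcRi for 17, and 11 were already called higher in EcRi wing at -30 h. Background cannot be told apart from EcR-RNAi, as WT carried neither driver nor hairpin. The EcR level was not called lower in EcRi wing. That EcR holds part of the prepupal wing programme back is a hypothesis that driver-only wings at -6 h would test.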

How the results depend on the processing

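The scaling, filter, fold minimum, library set, block and leave-one-out settings were planned; voom, log2(RPKM + 0.1), pseudocounts, limma treat, array weights, the omission of carry-over or fat body genes and the omission of WT gland -30 h replicate 2 from comparisons that do not hold it were chosen after seeing the data. The DESeq2 Wald test and edgeR glmTreat were not run, although reads had been recovered. Counts of genes were taken as kept within 1.5 times the main value. Of 323 alternative counts of 24 results, 256 were kept and 67 moved. Each of the 19 gene counts was kept under median-of-ratios scaling, TMM without glue and 71E genes, both filters and the replicate block. Replicate numbers were not taken to pair libraries, because deviations from group means in 45 pairs of groups did not all correlate above 0.1 across genes (-0.04 to 0.426, median 0.154). With 29 above 0.1 and 0 below -0.1, the data hint at a factor shared by libraries of the same number. With the block, EcRi against WT gave 186 genes in wing and 2787 in gland at -6 h.

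Without a fold minimum the moved counts were 2106 for EcRi gland at -30 h, 762 for EcRi gland over time and 394 for the shared temporal change in gland. With only the compared libraries in the fit, which leaves fewer residual degrees of freedom, the moved counts were 1055 for WT gland to -6 h, 785 for wing against gland at -30 h, 15 for EcRi gland at -30 h, 223 for genotype by time in wing, 1287 for genotype by time in gland, 107 for genotype by tissue at -30 h, 1635 for tissue by time to -6 h, 73 for the shared temporal change in gland and 9 for the shared RNAi response at -30 h. With only the libraries of the tissue the moved counts were 396 for EcRi wing at -30 h, 306 for EcRi wing at -6 h, 439 for EcRi gland at -30 h, 476 for EcRi wing over time, 143 for EcRi gland over time, 286 for genotype by time in wing, 1579 for genotype by time in gland, 303 for the shared temporal change in wing and 83 for the shared temporal change in gland. With voom the moved counts were 1979 for WT gland to +6 h, 11 for genotype by time in wing, 1262 for genotype by tissue at -6 h and 1433 for tissue by time to +6 h. On log2(RPKM + 0.1) the moved counts were 49 for genotype by time in wing. With a pseudocount of 4 the moved counts were 123 for EcRi wing at -30 h, 900 for EcRi gland at -30 h, 29 for the shared RNAi response at -30 h and 38 for the shared RNAi response at -6 h. With array weights the moved counts were 1806 for WT gland to -6 h, 1560 for wing against gland at -30 h, 432 for EcRi wing at -30 h, 345 for EcRi wing at -6 h, 130 for EcRi gland at -30 h, 492 for EcRi wing over time, 379 for genotype by time in wing, 1269 for genotype by time in gland, 149 for genotype by tissue at -30 h, 1481 for tissue by time to -6 h, 307 for the shared temporal change in wing, 15 for the shared RNAi response at -30 h and 123 for the shared RNAi response at -6 h. With limma treat against 2-fold, a stricter test by construction, the moved counts were 1766 for WT gland to -6 h, 1436 for WT gland to +6 h, 140 for WT wing to -6 h, 606 for WT wing to +6 h, 1406 for wing against gland at -30 h, 2803 for wing against gland at -6 h, 3029 for wing against gland at +6 h, 35 for EcRi wing at -30 h, 34 for EcRi wing at -6 h, 196 for EcRi gland at -30 h, 1179 for EcRi gland at -6 h, 68 for EcRi wing over time, 65 for EcRi gland over time, 8 for genotype by time in wing, 1015 for genotype by time in gland, 133 for genotype by tissue at -30 h, 749 for genotype by tissue at -6 h, 1076 for tissue by time to -6 h, 1172 for tissue by time to +6 h, 40 for the shared temporal change in wing, 38 for the shared temporal change in gland, 10 for the shared RNAi response at -30 h and 13 for the shared RNAi response at -6 h. Of the gene list tests, 222 passed with the preset correlation and 47 with an estimated one. Without WT gland -30 h replicate 2, a library that is not in these comparisons but shares their estimate of spread, the moved counts were 361 for EcRi wing at -30 h, 289 for EcRi wing at -6 h, 689 for EcRi gland over time and 192 for genotype by time in wing, and WT wing to -6 h and EcRi wing over time reached 704 and 451. Apart from the stricter test, the cause was not tested.

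Leaving out each compared library in turn leaves a group with a single library, which is assumed to vary like the other groups. The lowest and highest counts were 333 to 471 for WT wing to -6 h, 2631 to 4786 for wing against gland at -30 h, 97 to 220 for EcRi wing at -30 h, 34 to 119 for genotype by time in wing, 431 to 4107 for genotype by tissue at -30 h, 2435 to 4914 for tissue by time to -6 h, 91 to 141 for EcRi wing at -6 h, 151 to 235 for EcRi wing over time, 647 to 4014 for EcRi gland at -30 h, 2278 to 4755 for genotype by time in gland, 230 to 459 for EcRi gland over time, 97 to 166 for the shared temporal change in wing, 113 to 321 for the shared temporal change in gland, 23 to 97 for the shared RNAi response at -30 h and 34 to 63 for the shared RNAi response at -6 h. The cause was not tested.

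Of 7107 alternative values for 372 results of named genes, 6915 kept their direction and side of the threshold, 185 fell short of it, 4 newly passed and 3 changed sign, though genes were preferred whose calls survived leaving out each library, which favours this. The sign changes were all of EcR in EcRi gland at -30 h, a value near 0: -0.004 scaled without glue and 71E genes, -0.05 without WT gland -30 h replicate 1 and -0.045 without EcRi gland -30 h replicate 1. Without WT gland -30 h replicate 2 it was 0.064. Depth limits genes of few reads: a read in WT gland at -6 h stands for 0.22 and 0.23 scaled RPM, against 0.0284 to 0.135 in the other libraries.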

Other observations

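The values below were noticed after the data were seen and belong to no planned test. The non-coding RNA roX1, part of the dosage compensation machinery of males, was present in libraries labelled female, at 22.2 ± 0.071, 17.4 ± 23.5 and 20.3 ± 26.2 scaled RPM in WT wing at -30, -6 and +6 h, and 6.7 ± 1.95 and 1.04 ± 0.42 in EcRi wing. In gland lncRNA:roX1 stood at 0.285 ± 0.403, 15.5 ± 17.5 and 2.01 ± 1.71 in WT and 2.03 ± 0.607 and 0.874 ± 0.044 in EcRi.

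Serum protein genes made in fat body were abundant in gland libraries, and not to the same extent in each. Lsp1beta stood at 1976 ± 1029 scaled RPM in WT gland at -30 h and 6423 ± 1581 in EcRi gland at -30 h, and the lipoprotein gene apolpp at 1186 ± 686 and 3581 ± 769. At -6 h Lsp1beta stood at 1190.2 ± 252 in WT and 1062 ± 293 in EcRi gland, and apolpp at 523 ± 16.3 and 1039.6 ± 370.2.

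The genes CG32074, CG13445 and CG14143 remained high in EcRi gland at -6 h, at 23420.1 ± 19112, 5427 ± 4105 and 13474 ± 12411 scaled RPM, where WT gland held 66.1 ± 17.4, 8.97 ± 5.54 and 27.2 ± 7.74. In WT gland at +6 h they stood at 34.3 ± 3.92, 5.44 ± 0.269 and 19.4 ± 4.19. In dm6 the positions are: CG32074 (FBgn0052074, chromosome 3L, 11131883 to 11132322), CG13445 (FBgn0036532, chromosome 3L, 15809485 to 15809977) and CG14143 (FBgn0036138, chromosome 3L, 11134987 to 11135480).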
